A study of Mus musculus with 20 samples.

How the data were processed

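RNA sequencing libraries of FIPs and APCs, sorted from the gonadal white fat of control and Mural-Zfp423 transgenic mice, formed 4 groups of 5. Each library held RNA of 2 mice, so the pool is the replicate. At 10 mice per genotype and 2 per library, the 5 FIP and 5 APC pools of a genotype must share mice. Which pools share them is not stated, and the main fit described below took all libraries as independent. The values analysed are the log2 CPM (counts scaled to library size) as deposited in 1 table of 54304 genes and 20 libraries, given to 2 decimals, with CPM of 1 or less listed as 0. According to the authors, reads were trimmed with Trim Galore 0.4.1, aligned with HISAT2 2.0.1 to the mouse genome GRCm38, counted with featureCounts 1.4.6 and tested with DESeq2 1.6.3. The annotation release and the strand setting are not given in the sources used here. Names and coordinates were taken from GENCODE M21 (GRCm38), which matched 54276 of the table's genes. The 13 mitochondrial protein genes were at 0 everywhere, so mitochondrial reads cannot be used as a quality measure.

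Depth was estimated from the spacing of the lowest values, the step of 1 read. It lay between 6.61 and 8.5 megareads, so that 1 CPM was 6.61 to 8.5 reads. Between 15972 and 17282 genes exceeded 1 CPM in a library. Reads recovered from the low values were within 0.0051 log2 units of whole numbers for 76 to 79.1% of them. Because this fell short of nearly all, a count-model test was not applied. Within groups, 40 pairs of libraries correlated across genes at r = 0.9799 to 0.9945, with a chi-square per gene of 1.58 to 13.92 against counting noise.

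Genes above 0 in at least 5 libraries were kept (17435), and 34963 genes were 0 in every library. All 20 libraries were fitted together with 1 mean per group in limma 3.58.1 (R 4.3.3), with 16 residual degrees of freedom, a variance trend and Benjamini-Hochberg adjustment at 0.05. Comparisons were FIP against APC in each genotype, labelled transgenic against control in each cell type, and the genotype by cell type interaction. These comparisons, the lists and all but the last alternatives given below were fixed before the data were examined. Exact permutation tests used all splits of 10 libraries into 5 and 5, and the list scores were tested for interaction over all pairs of such splits in the 2 cell types.

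Of 36 lists fixed, 34 had at least 3 tested members. The mitochondrial and epididymal lists fell short and were not tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The score of a list in a library is the mean log2 CPM of its members. Genes are named by rule: Zfp423 and the gate genes; passing genes with the largest differences, with no overlap between the groups and a mean of at least 2 log2 CPM in the higher group, predicted genes excluded, up to 12 per direction in a main comparison and 6 in others; up to 6 members per list with the strongest evidence; and passing members of the inflammatory, interferon, matrix and progenitor lists. Alpl lies outside this rule and was added after the data were seen, because it had the smallest adjusted p between genotypes in FIPs and passed in APCs too. Some genes that meet the rule are not reported here, although every count includes them.

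Alternatives were an added 1 or 0.1 before the logarithm, no filter or a stricter one, libraries centred on their medians, quantile normalization, a trimmed mean of M-values shift, robust variance, array weights, only the groups compared, the replicate number as a block, pools as a random effect, and each library left out. Added after the data were seen were the erythroid or macrophage score as a covariate, list tests without replicate 5 of the FIPs labelled transgenic, and removal of the trend with gene length and GC content. The procedure was tested on simulated data with 200 changed genes. It recovered between 64.2 and 91% of changes of 0.5 log2 units across comparisons, between 95.5 and 98.5% of changes of 1 unit and all changes of 2 units, with 5 to 15 false calls, and called 0 genes when none were changed. The simulated noise was normal and independent between genes, with 1 SD per gene and no outlying library. Changes were placed only in genes of higher mean level, so the recovery does not apply to genes near 0 log2 CPM. In the real libraries genes vary together and single libraries stood apart, so false calls there can be more frequent. Exchanging replicate 1 of the 2 APC groups gave 2803 calls.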

Results

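Gene expression was measured by RNA sequencing of polyadenylated RNA in 2 sorted populations of PDGFRβ-expressing stromal cells from the gonadal white fat of male mice. Fibro-inflammatory progenitors (FIPs) carried LY6C on their surface. Adipogenic precursor cells (APCs) carried neither LY6C nor CD9. CD45-positive blood cells and CD31-positive endothelial cells were gated out of both. The mice were either controls or Mural-Zfp423 transgenics, a line named for expression of the transcription factor Zfp423 in mural cells, the perivascular cells of small vessels. They were 8 weeks of age in the labels, were housed at 30 °C and had eaten a diet with 60% of its calories from fat for 1 month. Each library held RNA of 2 mice, 10 mice were used per genotype, and each of the 4 groups had 5 libraries. The depth, estimated from the spacing of the lowest values, lay between 6.61 and 8.5 megareads per library. It was 7.6 to 8 megareads in control APCs, 6.61 to 8.38 in APCs labelled transgenic, 6.76 to 8.24 in control FIPs and 7.82 to 8.5 in FIPs labelled transgenic. Depth did not separate the genotypes (exact permutation test, two-sided, p = 0.857 in APCs and p = 0.127 in FIPs). Between 15972 and 17282 genes exceeded 1 CPM (counts scaled to library size) in a library, and 17435 genes were tested. The first principal component held 56.7% of the variance and separated FIPs from APCs.

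Zfp423, the gene the transgene carries, was examined first because its level bears on the genotype labels. Its gene spans 87661810 to 87959595 on chromosome 8 (GRCm38). In FIPs it stood at 5.53 ± 0.04 log2 CPM (mean ± SD, n = 5) in libraries labelled transgenic and 5.47 ± 0.12 (n = 5) in controls. The difference was 0.06 log2 units, with a 95% confidence interval of −0.16 to 0.27, so its upper bound was a 1.21-fold increase (limma, Benjamini-Hochberg adjusted p = 0.933; exact permutation p = 0.381). In APCs it stood at 4.70 ± 0.27 in libraries labelled transgenic and 4.97 ± 0.17 in controls, a difference of −0.26 with an interval of −0.48 to −0.05 (limma adjusted p = 0.108; exact permutation p = 0.103, n = 5 per group). A rise of Zfp423 messenger RNA was not measured in either population, and its value in APCs lay on the opposite side from the label. Whether reads of the transgene are counted under the annotated gene is not given in the sources used here, so this value does not settle the labels. For this reason the libraries are called labelled transgenic throughout, and every genotype direction given here rests on the labels and not on Zfp423. Without replicate 1 of the APCs labelled transgenic the difference was −0.38, and it passed in limma.

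**Figure D1:**
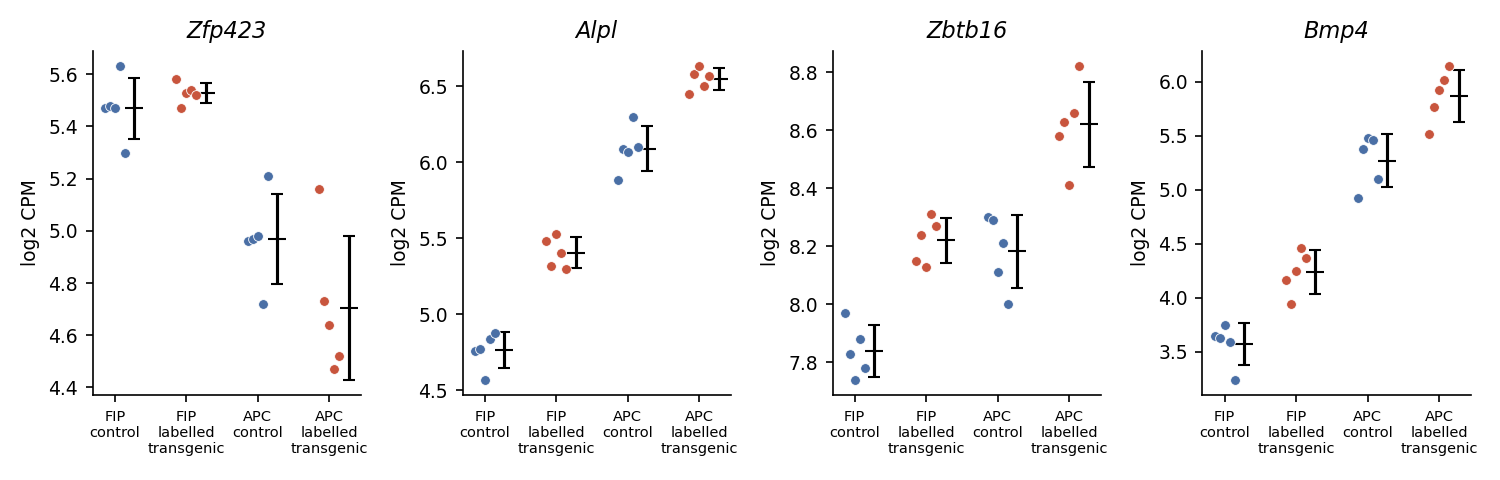
Expression of Zfp423, Alpl, Zbtb16 and Bmp4 in log2 CPM (vertical axes, each with its own range) in each library, by group; points are libraries, and the bars beside them give the mean and SD of 5 libraries. Zfp423 overlapped between genotypes in both populations, whereas all 5 Alpl values labelled transgenic lay above all 5 controls in FIPs and in APCs.

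The comparison of FIPs with APCs in control mice described the 2 populations at the baseline of the model. Markers of interstitial progenitors, the collagen-rich adventitial cells that lie upstream of preadipocytes, were higher in FIPs in all 19 cases. Cd55, a complement inhibitor, stood at 9.07 ± 0.06 log2 CPM in FIPs and 6.38 ± 0.15 in APCs (n = 5 each), a difference of 2.70 (SE 0.06). Dpp4, a surface peptidase, differed by 2.67 and Pi16 by 2.34. Genes of the adipocyte lineage lay the other way: Pparg, the master regulator of fat cell differentiation, was 5.25 ± 0.11 in FIPs and 6.38 ± 0.19 in APCs (−1.13, SE 0.11), and the fatty acid carrier Fabp4 differed by −0.73. The mural cell genes Notch3, a receptor of vascular smooth muscle and pericytes (−1.26), and Des, an intermediate filament protein (−1.10), were also lower in FIPs. In limma, 8288 of 17435 genes passed at an adjusted p of 0.05, 3422 higher and 4866 lower in FIPs, and 5467 genes (31.4%) had no overlap between the groups, against 0.79% by chance.

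Among genes without overlap, Duox1, an oxidase that makes hydrogen peroxide, had the largest difference between control FIPs and control APCs. It stood at 7.13 ± 0.27 log2 CPM in FIPs and 1.19 ± 0.72 in APCs, a difference of 5.94 (SE 0.26, limma adjusted p = 1.64e-13). Its maturation factor Duoxa1 was higher too, though listed at 0 in 1 APC library. The extracellular protease Adamts16 differed by 5.47, the guidance factor Sema3e by 5.14, the matricellular protein Nov by 5.12, the Wnt antagonist Dact2 by 5.04 and the Wnt ligand Wnt10b by 4.97. Islr2 and Nptx2 each differed by 4.45. Mrgprg, Fam167a and Nefl were listed at 0 in all APCs of the controls, so no fold is given. In the other direction, Cnmd, which encodes chondromodulin, was 2.59 ± 0.58 in FIPs and 6.08 ± 0.15 in APCs (−3.48, limma adjusted p = 1.99e-11). St8sia6 differed by −3.24, Dok7 by −3.10, Pde4c by −3.03, Shisa6 by −2.90, the smooth muscle gene Lmod1 by −2.88, Lrrn1 by −2.79 and the laminin gene Lamc3 by −2.66. Ntf3, Pcdh8 and the Hedgehog antagonist Hhip were lower as well, but they were listed at 0 in some FIP libraries, and Pgbd5 was listed at 0 in all control FIPs.

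Among the fixed gene lists, the interstitial progenitor list was higher in FIPs with a median difference of 2.67 (camera in limma, adjusted p = 4.53e-26; adjusted p = 2.9e-05 with an estimated correlation; 19 of 19 genes adjusted over the list alone). Committed preadipocyte markers were lower for 14 of 17 genes and higher for 2 in both counts, over all genes and adjusted over the list alone (median −0.40; camera adjusted p = 7.31e-05; adjusted p = 0.149 with an estimated correlation). The adipocyte lipid program was lower for 28 of 30 genes and 29 adjusted over the list alone (median −0.65; camera adjusted p = 2.93e-07; adjusted p = 0.432 with an estimated correlation). Mural cell markers were lower for 21 of 22 genes by either count, over all genes or adjusted over the list alone (median −0.89; camera adjusted p = 1.19e-09; adjusted p = 0.0523 with an estimated correlation). Interferon response genes were higher for 25 of 31, and also 25 adjusted over the list alone (median 0.92; camera adjusted p = 1.27e-13; adjusted p = 0.26 with an estimated correlation). Ifi44 differed by 3.63 and Ifit3, an antiviral RNA-binding protein, by 2.51. Cholesterol biosynthesis genes were higher for 16 of 24 and lower for 2, with the same counts adjusted over the list alone (median 0.32; camera adjusted p = 1.79e-05; adjusted p = 0.432 with an estimated correlation). Matrix glycoproteins and proteoglycans were higher for 19 of 35 genes and lower for 5, again with the same counts adjusted over the list alone (camera adjusted p = 1.3e-07; adjusted p = 0.188 with an estimated correlation). Fbn1 was higher by 0.52 and Spp1 by 3.89, whereas Fmod differed by −1.28.

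Transcripts of other cell types also differed between the 2 populations of the control mice. All 6 erythroid genes were lower in FIPs, over all genes and adjusted over the list alone (median −1.27; camera in limma, adjusted p = 0.0027; adjusted p = 0.432 with an estimated correlation), and alpha-globin Hba-a1 stood at 7.09 ± 0.08 log2 CPM in FIPs and 8.36 ± 0.43 in APCs (n = 5 each). Endothelial markers were lower for 18 of 21 genes by either count, over all genes or adjusted over the list alone (median −0.61; camera adjusted p = 0.00111; adjusted p = 0.432 with an estimated correlation). The gate genes were measured as a check on the sort and are not findings: in limma, FIPs against APCs gave 2.25 for Ly6c2, 1.71 for Ly6c1, 1.54 for Cd9, −0.45 for Pdgfrb, −0.63 for Pecam1 (adjusted p = 0.000716) and −0.48 for Ptprc (adjusted p = 0.143). For FIP against APC in control mice with the erythroid score of each library as a covariate, 4156 genes passed in place of 8288, of which 3706 were shared. Centring each library on its median changed the share of higher calls from 41.3% to 52.8%.

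The comparison of FIP against APC in transgenic mice, by label, asked whether the 2 populations stayed distinct. Cd55 was again higher in FIPs (8.89 ± 0.04 against 6.14 ± 0.10 log2 CPM, n = 5 each, difference 2.75, SE 0.06), as were Dpp4 (2.95) and Pi16 (3.07), while Pparg (−0.81) and Notch3 (−1.46) were lower. Apart from genes listed at 0 in some libraries, the named genes with the largest differences were Adamts16 (6.20), Nov (5.97) and Sema3e (5.70) on the higher side and Cnmd (−3.53), Blnk (−3.35), Pde4c (−3.26) and Dok7 (−3.18) on the lower side. Duox1, Wnt10b, Pcdh8 and Ntf3 also passed but were listed at 0 in some libraries of the lower group, and Mrgprg was listed at 0 in all of these APCs. Of these, Duox1 (6.46) and Pcdh8 (−3.77) differed by more than the genes given before. All 19 interstitial progenitor markers were higher, also adjusted over the list alone (median 2.81; camera in limma, adjusted p = 2.38e-23; adjusted p = 5.86e-05 with an estimated correlation). Interferon response genes were higher for 17 of 31 and for 18 adjusted over the list alone (median 0.41; camera adjusted p = 0.000633; adjusted p = 0.69 with an estimated correlation). Mural cell markers were lower for 16 of 22 and higher for 1, or lower for 17 adjusted over the list alone (median −0.50; camera adjusted p = 6.17e-06; adjusted p = 0.134 with an estimated correlation). In limma, 7275 genes passed, 3962 higher and 3313 lower in FIPs, and 5050 (29%) did not overlap, against 0.79% by chance. The calls shared with the control mice were 2841 on the higher side, where independent lists would share 777.63, and 2573 on the lower side, where they would share 924.64, with 8 genes called in opposite directions. Across genes, the differences of the 2 comparisons correlated with Pearson r = 0.88 and Spearman rho = 0.81; genes are not independent replicates. Centring changed the share of higher calls from 54.5% to 43.8%.

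The comparison of genotypes within FIPs asked whether the inflammatory and fibrotic programs of these cells differed in mice of the Mural-Zfp423 line. Of 31 interferon response genes 7 fell in the libraries labelled transgenic. Oas3, a sensor of double-stranded RNA, stood at 2.22 ± 0.67 log2 CPM against 4.08 ± 0.51 in controls (n = 5 each), a difference of −1.85 (SE 0.29, limma adjusted p = 0.00759). The dynamin-like antiviral GTPase Mx1 stood at 2.22 ± 1.10 against 4.15 ± 0.44 (−1.93, SE 0.40, limma adjusted p = 0.0367), and Ifit3 at 5.85 ± 0.74 against 7.15 ± 0.25 (−1.31, SE 0.24, adjusted p = 0.0201). Ifi44 (−1.64), Rsad2 (−1.10), the GTPase Igtp (−0.62) and the RNA sensor Ifih1 (−0.32) also passed. With 1 library left out, Oas3 passed in all 10 fits, Ifit3 lost the threshold in 3, Ifi44 in 7, and Mx1, Rsad2, Igtp and Ifih1 in 8 each. With the replicate number as a block, most of the 7 calls were lost. Of the 31 measured members, 7 were lower over all genes and 25 adjusted over the list alone (median −0.42; camera in limma, adjusted p = 1.56e-31; adjusted p = 0.0918 with an estimated correlation). The mean over the list was 5.36 ± 0.38 against 5.94 ± 0.18 log2 CPM, a difference that did not pass (exact permutation p = 0.0317, Benjamini-Hochberg adjusted p = 0.216 over 34 lists). Replicate 5 of the FIPs labelled transgenic did not follow the others: its mean over the list was 6.01 log2 CPM, against 5.04 to 5.31 in the other 4 and 5.64 to 6.10 in the controls. Without that library 19 members were lower, with a median of −0.55 and adjusted p = 0.00165 with an estimated correlation in camera. It was left out because of its values in these same genes, so this smaller p does not test them independently. Macrophage markers moved beside this group, with a median of −0.48 over 24 genes, of which limma called 0 (13 lower at an unadjusted p under 0.05; camera adjusted p = 1.48e-14; adjusted p = 0.498 with an estimated correlation; fry adjusted p = 0.213).

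**Figure D2:**
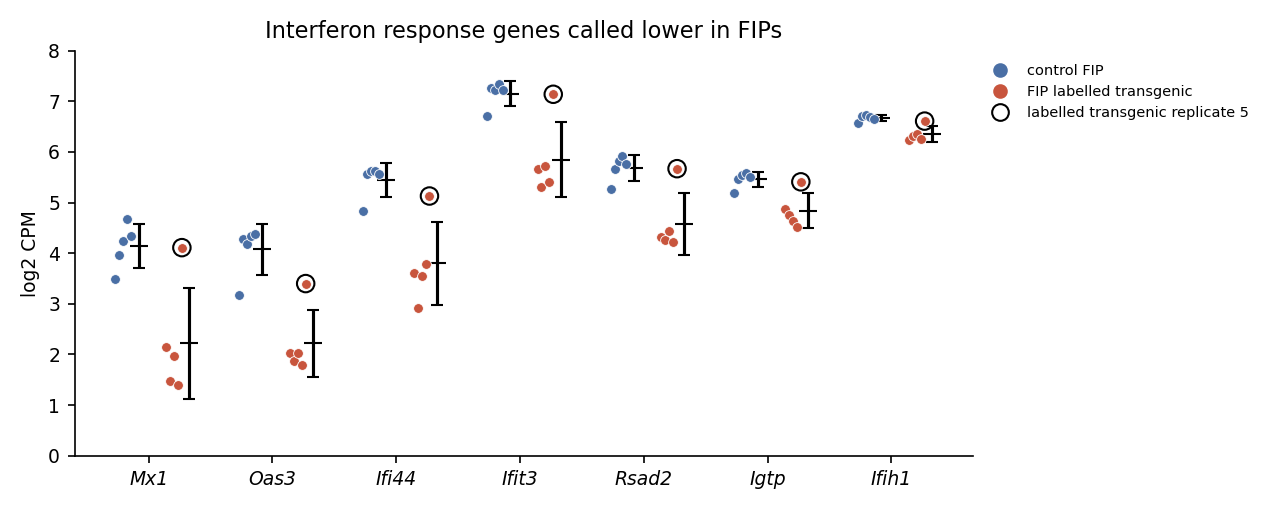
Expression in log2 CPM (vertical axis) of the 7 interferon response genes that passed in FIPs, in each control library and each library labelled transgenic; bars give the mean and SD of 5 libraries, and rings mark replicate 5 of the libraries labelled transgenic. The ringed library lies within the control range for each of the 7 genes, for example at 7.14 for Ifit3, where the control mean is 7.15.

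Among genes without overlap between the groups, Igfbp3, which binds insulin-like growth factors, was 1 of those that rose most in FIPs labelled transgenic, by 1.19 (SE 0.15, limma adjusted p = 0.000797), from 6.02 ± 0.18 to 7.20 ± 0.38 log2 CPM (n = 5 each). In limma the fibrillar collagen gene Col11a1 rose from 1.05 ± 0.56 to 2.65 ± 0.64 (adjusted p = 0.00759), the laminin gene Lama1 by 1.38 (adjusted p = 0.0366), the collagenase Mmp8 by 1.14 from 1.01 ± 0.45 and the collagen hydroxylase P4ha3 by 0.85. The fixed matrix lists, given below, did not rise as sets. Kif26b rose by 1.62, the adhesion receptor Selp by 1.47, Kng1 by 1.16, Asic3 by 1.06, Kcne4 by 1.04, the iron exporter Slc40a1 by 0.91 and the receptor kinase Epha2 by 0.88. Alkaline phosphatase Alpl (0.64, adjusted p = 0.000147), the growth factor Bmp4 (0.67, adjusted p = 0.0277) and the transcription factor Zbtb16 (0.38, adjusted p = 0.0157) rose in limma as well. Fam167a fell by 0.77, Flnc by 0.23, the Notch receptor Notch2 by 0.22, Cxxc5 and Dact1 each by 0.21, the ubiquitin ligase Smurf1 by 0.19, and Rbpj, the nuclear effector of Notch, by 0.16. With 1 library left out, Igfbp3, Col11a1, Kcne4 and Epha2 passed in all 10 fits. Kif26b lost the threshold in 1, Mmp8 in 2, Fam167a and Notch2 in 3, P4ha3 and Flnc in 5, Cxxc5 in 6, Kng1 and Rbpj in 7, Selp, Lama1, Asic3, Dact1 and Smurf1 in 8, and Slc40a1 in 9.

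Further lists were compared between genotypes in FIPs. Of 29 fibrillar collagen and crosslinking genes, 11 lay above 0 and 18 below (median −0.04). In limma 1 was higher, and 3 adjusted over the list alone (fry adjusted p = 0.955). Matrix glycoproteins and proteoglycans had a median of −0.04 over 35 genes. Limma called 0, with 4 higher and 1 lower adjusted over the list alone (fry adjusted p = 0.769). Basement membrane genes had a median of −0.06 over 20 genes, with 0 called (camera adjusted p = 0.00379, fry adjusted p = 0.34). Of 39 NF-kB target genes limma called 0 over all genes, while 10 had an unadjusted p under 0.05 and 1, Saa3 (−1.01, adjusted p = 0.0826), was lower adjusted over the list alone (camera adjusted p = 0.519; fry adjusted p = 0.769). Of 35 toll-like receptor and NF-kB pathway components 1 was lower, the kinase Ikbkb (−0.25, limma adjusted p = 0.0277), and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.849). The adipocyte lipid program had a median of −0.15 over 30 genes: limma called 0 over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 (camera adjusted p = 5.4e-07; adjusted p = 0.555 with an estimated correlation; fry adjusted p = 0.62). Mesothelial markers had a median of −0.20 over 19 genes: limma called 0 by either count, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.00708; adjusted p = 0.555 with an estimated correlation; fry adjusted p = 0.62). Endothelial markers had a median of 0.32 over 21 genes: limma called 0 over all genes, 12 had an unadjusted p under 0.05, and 10 were higher adjusted over the list alone (camera adjusted p = 3.3e-06; adjusted p = 0.498 with an estimated correlation; fry adjusted p = 0.213). Mural cell markers had a median of 0.12 over 22 genes: limma called 0 over all genes, 7 had an unadjusted p under 0.05, and 3 were higher adjusted over the list alone (camera adjusted p = 0.00766; adjusted p = 0.498 with an estimated correlation; fry adjusted p = 0.213). All 19 interstitial progenitor markers had a lower mean than in controls, with a median of −0.12; limma called 0 over all genes and 0 adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 3.3e-06; adjusted p = 0.0866 with an estimated correlation; fry adjusted p = 0.0481).

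For transgenic against control in FIPs, 65 genes passed in limma, 42 higher and 23 lower in the libraries labelled transgenic, and 503 (2.9%) did not overlap, against 0.79% by chance. The count depended on single libraries. Without replicates 1, 3, 4 or 5 of the FIPs labelled transgenic it was 18, 35, 9 and 125, and without control replicates 2, 3, 4 or 5 it was 35, 35, 14 and 27. It was 36 when only the 10 FIP libraries entered the fit and 271 with array weights.

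The comparison of genotypes within APCs asked the same of the adipogenic cells. Some markers of other cell types fell in the libraries labelled transgenic. Hba-a1 stood at 7.39 ± 0.47 log2 CPM against 8.36 ± 0.43 in controls (n = 5 each; −0.97, SE 0.21, limma adjusted p = 0.0174), and all 6 erythroid genes passed, over all genes and adjusted over the list alone (median −0.94; camera adjusted p = 9.08e-06; adjusted p = 0.371 with an estimated correlation). Adgre1, the macrophage adhesion receptor, stood at 3.61 ± 0.37 against 4.61 ± 0.41 (SE of the difference 0.24, limma adjusted p = 0.022), and the receptor Csf1r differed by −0.85. Of 24 macrophage markers 13 fell over all genes and 22 adjusted over the list alone (median −0.74; camera adjusted p = 9.1e-11; adjusted p = 0.371 with an estimated correlation). Of 19 mesothelial markers 6 fell, including the keratin Krt7 (−1.02) and Lrrn4 (−1.07), and 12 fell and 1 rose adjusted over the list alone (median −0.74; camera adjusted p = 4.46e-05; adjusted p = 0.371 with an estimated correlation). Of 30 genes of the adipocyte lipid program 18 fell, and 28 adjusted over the list alone (median −0.43; camera adjusted p = 8.36e-12; adjusted p = 0.391 with an estimated correlation). Among them the fatty acid synthesis genes Acaca and Fasn fell by 0.61 and 0.34, and the glycerol phosphate dehydrogenase Gpd1 by 0.64. The erythroid, macrophage, mesothelial and adipocyte lipid lists together held 43 lower calls. They held 5 with the replicate number as a block, and 0 with the erythroid or the macrophage score as a covariate. Of 21 endothelial markers 1 was higher and 1 lower over all genes, and 1 and 2 adjusted over the list alone (camera adjusted p = 0.0545; fry adjusted p = 0.238). Of 13 lymphocyte markers 1 fell, also adjusted over the list alone; under quantile normalization this call and the higher endothelial call were lost (camera adjusted p = 0.00515; adjusted p = 0.391 with an estimated correlation). Of 9 Schwann and neural markers limma called 0 over all genes, with 5 at an unadjusted p under 0.05, and 1 was higher and 4 lower adjusted over the list alone (camera adjusted p = 0.155; fry adjusted p = 0.0313).

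**Figure D3:**
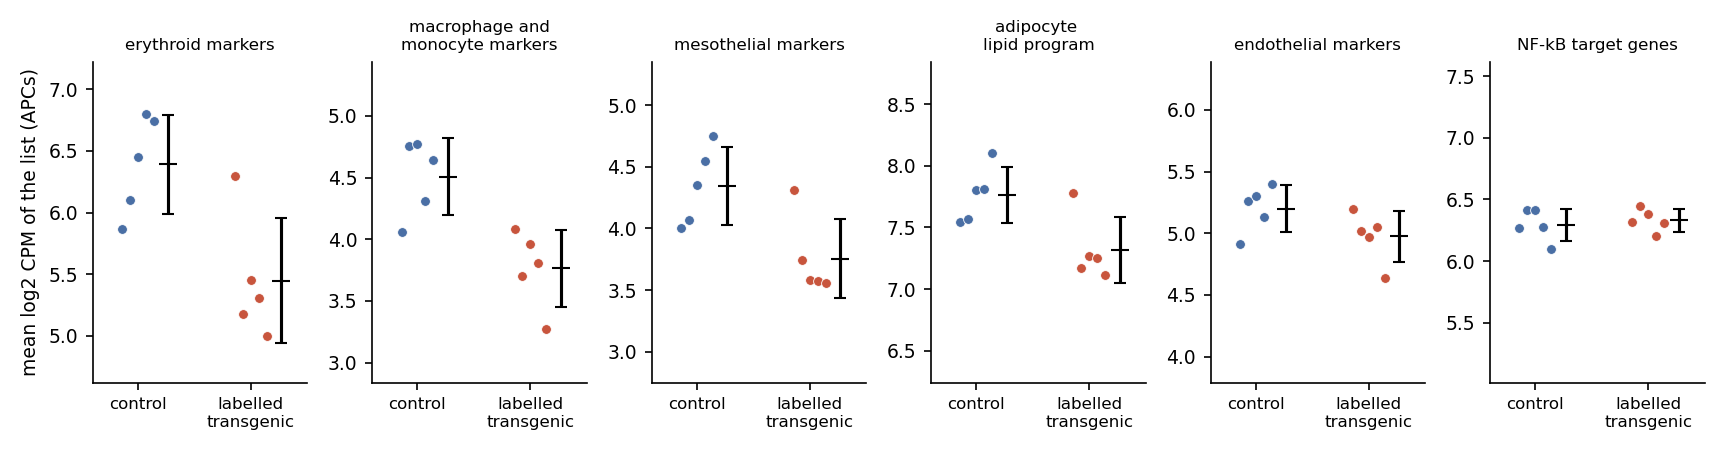
Mean log2 CPM of 6 marker lists (vertical axes, with equal spans) in each control APC library and each APC library labelled transgenic; points are libraries, bars the mean and SD of 5 libraries. Erythroid, macrophage, mesothelial and adipocyte lipid scores were lower on average in the libraries labelled transgenic, while replicate 1 of both groups lay toward the other group.

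Single genes of further lists also passed between genotypes in APCs. The interstitial progenitor marker Pi16 fell by 0.74 in libraries labelled transgenic (5.08 ± 0.25 against 5.81 ± 0.27 log2 CPM, n = 5 each, limma adjusted p = 0.00196), Dpp4 by 0.41 and Cd248 by 0.28. Of 19 such markers 7 fell and 1 rose over all genes, and 10 fell and 1 rose adjusted over the list alone, with Creb5, which rose by 0.27, failing under quantile normalization (camera adjusted p = 0.000526; adjusted p = 0.286 with an estimated correlation). Bmp4 rose by 0.60 (limma adjusted p = 0.0164), Alpl by 0.46 and Zbtb16 by 0.44 (both adjusted p = 0.00231), and the glucocorticoid-induced chaperone partner Fkbp5 by 0.40. Of 39 NF-kB target genes 6 rose, and 8 adjusted over the list alone, by small amounts: the adhesion molecules Vcam1 and Icam1 by 0.25 and 0.29, and the NF-kB subunits Nfkb1 and Relb by 0.22 and 0.27 (list median 0.08; camera adjusted p = 4.46e-05; adjusted p = 0.391 with an estimated correlation). Of 31 interferon response genes only Irf9 passed, with 0.26, and limma called 0 adjusted over the list alone (camera adjusted p = 0.0705; fry adjusted p = 0.736). Among genes without overlap between the groups, those that rose most were Ppm1n (1.28), Gnat2 (0.88), Nup210l (0.87), Bicdl2 (0.85), Icam5 (0.82), Mtfr2 (0.81), Slco1a4 (0.77), St8sia6 (0.60), Lag3 (0.59) and Fanci (0.58). Those that fell most were Rgs1 (−1.42), Amn and Wwc1 (both −1.17), Shtn1 and the RNA sensor Tlr7 (both −1.07), Dnajc12 (−1.04), the Wnt modulator Dkk3 (−1.01), Fam110c (−0.97), Ptpro (−0.94), and Ptafr and Nfam1 (both −0.92). With 1 library left out, Rgs1 and Nfam1 lost the threshold in 8 of 10 fits, Ptpro and St8sia6 in 7 and Fam110c in 5, while Ppm1n, Gnat2, Nup210l, Bicdl2, Fanci, Amn and Shtn1 passed in all. Of the gate genes, those of LY6C and CD9, which APCs were sorted to lack, fell: Ly6c1 by 0.53, Ly6c2 by 0.53 and Cd9 by 0.65. These gate genes and all 19 interstitial progenitor markers were higher in FIPs than in APCs of the controls. Whether the share of FIPs in the APC libraries differed between genotypes was not tested.

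For transgenic against control in APCs, 1396 genes passed in the limma fit of all 20 libraries, 366 higher and 1030 lower in those labelled transgenic, and 509 (2.9%) did not overlap, against 0.79% by chance. The count did not hold outside that fit. With only the 10 APC libraries in the fit limma called 0 genes, with a smallest adjusted p of 0.0855, although 3602 had an unadjusted p under 0.05, including all 1396 with the same sign. With the erythroid score as a covariate it was 5, and with the macrophage score 11. Without replicates 1 to 5 of the APCs labelled transgenic it was 2849, 268, 559, 470 and 191, and without control replicates 1, 3, 4 or 5 it was 2471, 376, 603 and 181. The share of higher calls was 26.2% as deposited and 62.6% with libraries centred on their medians.

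Whether genotype acted differently in FIPs and APCs was tested as a genotype by cell type interaction. The mean over 29 Wnt and Hedgehog signaling genes was 4.40 ± 0.06 log2 CPM in FIPs labelled transgenic and 4.25 ± 0.05 in control FIPs, but 3.51 ± 0.14 and 3.72 ± 0.03 in the corresponding APCs (n = 5 each). The genotype differences were 0.15 and −0.22, and they differed by 0.36 (permutation of genotype within cell types, p = 0.000189, Benjamini-Hochberg adjusted p = 0.00643 over 34 lists). Labels were permuted in FIPs and APCs independently, so the permutation p-values given here hold only if their pools came from different mice. By the mouse counts FIP and APC pools of a genotype share mice. These p-values therefore do not decide whether the genotype differences differ between the populations. In limma 0 of the 29 Wnt and Hedgehog genes passed, with 9 at an unadjusted p under 0.05 and 7 adjusted over the list alone (camera adjusted p = 0.00677, adjusted p = 0.368 with an estimated correlation, fry adjusted p = 0.0304). For the interferon list the corresponding means gave −0.58 in FIPs and 0.02 in APCs, a difference of −0.60 that did not pass (permutation adjusted p = 0.115). Mural cell markers differed by 0.36 (permutation adjusted p = 0.0541) and endothelial markers by 0.46 (permutation adjusted p = 0.0827). For the interaction of single genes the smallest adjusted p in limma was 0.0669, shared by Igfbp3 and the gate gene Cd9. Their genotype effects differed between FIPs and APCs by 1.3 log2 units (2.46-fold) and 0.67 log2 units (1.59-fold). Limma therefore called 0 of 17435 genes, while 2388 had an unadjusted p under 0.05. Single libraries decided this too: 331 genes passed without replicate 1 of the APCs labelled transgenic, 70 without control APC replicate 1 and 32 without replicate 5 of the FIPs labelled transgenic. Counts of 1 to 3 were reached without replicates 3 and 5 of the APCs labelled transgenic (1 and 2), replicates 2 and 3 of the FIPs labelled transgenic (2 and 1) and control APC replicates 3 and 4 (1 and 3), and array weights gave 176. With the pool as a random effect, which takes FIP and APC pools of the same genotype and number to share mice, it was 36; the labels do not state this.

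Genotype differences in the 2 populations were also set side by side. These comparisons share no library, but by the mouse counts their FIP and APC pools share mice, so they are not independent. Across genes, which are not independent replicates, the genotype differences correlated weakly (Pearson r = 0.28, Spearman rho = 0.21). The calls shared were 6 genes higher in both, where independent lists would share 0.88, and 3 lower in both, where they would share 1.36, and none were opposite. Alpl, Bmp4 and Zbtb16 were among those higher in libraries labelled transgenic in both populations. Cxxc5 (−0.21 in FIPs and −0.24 in APCs) and the actin crosslinker Flnc (−0.23 and −0.14) were among those lower in both. The other 4 shared genes fall outside the rule for named genes.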

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

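The tests in this part followed fixed rules, and the weighing of the results flagged by them was chosen after they were seen. A library was named when the Dixon statistic of its group exceeded 0.71, which by chance happens in about 1 in 20 groups. It did so in 25 of 308 groups, where 15.4 would be expected, and 22 of them are given here.

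Replicate 1 of the APCs labelled transgenic stood apart most often. Its Dixon statistic was 0.778 for Pdgfrb, 0.781 for interstitial progenitor markers, 0.836 for committed preadipocyte markers, 0.763 for the adipocyte lipid program, 0.711 for complement, 0.769 for mesothelial markers and 0.882 for lymphocyte markers. It was 0.786 for oxidative phosphorylation, 0.742 for the antioxidant response, 0.795 for growth factors and 0.88 for Wwc1. Control APC replicate 1 gave 0.896 for fibrillar collagens and 0.765 for cell cycle genes. Replicate 4 of the APCs labelled transgenic gave 0.753 for cholesterol biosynthesis, and control APC replicate 5 gave 0.77 for Mtfr2.

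Replicate 5 of the FIPs labelled transgenic gave 0.721 for interferon response genes and 0.756 for Epha2, and replicate 1 of that group gave 0.824 for Flnc. Control FIP replicate 3 gave 0.725 for committed preadipocyte markers and 0.723 for Mmp8, and replicate 5 gave 0.806 for BMP signaling and 1 for Pcdh8, which was at 0 in the other libraries.

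The genotype difference in FIPs minus that in APCs passed for the Wnt and Hedgehog score, with 0.36, in a permutation that takes FIP and APC pools to be of different mice. The mouse counts go against that, so this pass does not hold as given. In camera 21 lists passed, of which 0 did with an estimated correlation. Median differences were higher in FIPs for gate genes (0.42), the adipocyte lipid program (0.28), Wnt and Hedgehog genes (0.30), mural (0.42), mesothelial (0.48), neutrophil and mast cell (0.72), endothelial (0.55) and erythroid markers (0.72), oxidative phosphorylation (0.14) and glycolysis (0.16). They were lower, or near 0 and below the other genes, for NF-kB targets (−0.07), toll-like receptor components (0), interferon response (−0.44), MHC class I (−0.06), fibrillar collagens (−0.07), matrix glycoproteins (−0.06), basement membrane (−0.10), metalloproteinases (−0.04), immediate early genes (−0.10), cell cycle (−0.22) and the unfolded protein response (−0.06).

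The lower values of interferon response genes in FIPs labelled transgenic might reflect less macrophage RNA, a wrong label of replicate 5 or gene length. With the macrophage score as a covariate the median of the list was −0.48, against −0.42 without it, so the difference did not shrink. The covariate had a common slope over all 20 libraries. Replicate 5 joined the lowest macrophage score of the FIPs (3.05) to an interferon score of 6.01, which can shift that slope. The covariate therefore cannot tell whether macrophage RNA had a part. With the length and GC trend removed 10 members were lower, which speaks against length and GC. In replicate 5, 58.9% of 90 genes called without it lay nearer to the labelled transgenic mean (exact interval 48 to 69.2%). The list and other genes named after interferon-induced families were left out of these 90. The interval takes genes as independent, which they are not, so it is too narrow. This share cannot tell whether the label is wrong.

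The fall of erythroid, macrophage, mesothelial and adipocyte lipid genes in APCs labelled transgenic might reflect a smaller share of RNA of other cells in these libraries. With the erythroid score as a covariate the median of the called genes was 0.18 in the direction of the call, against 0.54 without it, while the median SE was 0.15 against 0.14. All 6 erythroid genes were themselves among the called genes. A score that differs between the labels takes up part of any difference between them. The covariate therefore cannot tell RNA of other cells from a genotype difference in APCs. Whether the share changed alike for every cell type was not settled. The macrophage and endothelial scores changed by amounts that differed by −0.52 (SE 0.10, exact permutation p = 0.00794, n = 5 per group, adjusted p = 0.0595). This pair was picked as the most separated of all pairs of other-cell scores, and it did not pass after adjustment. With the length and GC trend removed 45 members of the lists were lower, against 43, which speaks against length and GC. Swapped labels of replicate 1 would have put the labelled transgenic library below the control for the genes called in FIPs, but it lay 0.14 above.

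The genes called in the same direction in both cell types, which number 9, could come from a chromosome region that differs between the mouse lines. The smallest adjusted p over whole chromosomes was 0.738 (exact binomial test, which takes genes as independent). No chromosome held more than 2 of the 9, and chromosomes 4 and 6 held 2 each. A test of whole chromosomes cannot detect a region of a few genes, so it does not settle this.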

How the results depend on the processing

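The tests with covariates, without replicate 5 of the FIPs labelled transgenic and with the length and GC trend removed were chosen only after the results were seen. The cause of the changes below was not tested. The count-model alternative was not run. In none of the results under the alternatives did a call pass in the opposite direction or a passing value change sign, apart from the scalings: there the sign changed for 2 of 298 called named genes for FIP against APC in control mice and 1 of 257 in transgenic mice. Under the alternatives, 1809 named-gene results kept their side and 362 lost the threshold.

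For transgenic against control in FIPs the main count was 65. It was 36 with only the groups compared, 271 with array weights, 107 with the erythroid and 115 with the macrophage covariate, and 9 to 125 with 1 library left out. The share of higher calls was 64.6%, and 51.9% with centring, 53.6% with quantile normalization and 53.6% with the trimmed mean shift. In the list tests 10 lists passed, 0 with an estimated correlation, 2 with fry, and 1 with an estimated correlation without replicate 5 of the FIPs labelled transgenic.

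For transgenic against control in APCs the main count was 1396. It was 812 without a filter, 2199 with centring, 0 with only the groups compared, 2253 with array weights, 320 with the replicate block, 5 with the erythroid and 11 with the macrophage covariate, 2657 with the length and GC trend removed, and 181 to 2849 with 1 library left out. The share of higher calls was 26.2%, and 62.6% with centring, 46.3% with quantile normalization and 39.0% with the trimmed mean shift. With an estimated correlation 0 of 17 lists passed. Zfp423 in APCs was −0.28 with array weights and −0.38 to −0.20 with 1 library left out.

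For FIP against APC in control mice the main count was 8288, and 4156 with the erythroid covariate. Ptprc was −0.61 with array weights, −0.48 with the replicate block, where it passed, and −0.66 to −0.30 with 1 library left out. Pecam1 was −0.16 with the erythroid covariate. Of 17 lists 1 passed with an estimated correlation, and 28 lists passed with fry. For FIP against APC in transgenic mice 1 of 15 lists passed with an estimated correlation.

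For the genotype by cell type interaction the main count was 0 in limma, with 2388 genes at an unadjusted p under 0.05. It was 1 with quantile normalization, 176 with array weights, 25 with the replicate block, 36 with the pool as a random effect, 2 with the erythroid and 1 with the macrophage covariate, and 0 to 331 with 1 library left out. Of 21 lists 0 passed with an estimated correlation, 3 with fry, and 1 with an estimated correlation without replicate 5 of the FIPs labelled transgenic. The median over all genes was 0.052 and became −0.064 with centring.

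After group means were removed, FIP and APC libraries of the same replicate number correlated at 0.04 to 0.27 in controls and 0.06 to 0.33 in mice labelled transgenic, against medians of −0.02 and −0.03 for other numbers. Libraries of different genotype correlated at −0.01 to 0.11 in FIPs and −0.32 to 0.15 in APCs. Not every pair exceeded 0.1 and not every library correlated best with its own number, so the numbers were not treated as pairs. By the mouse counts FIP and APC pools of a genotype share mice, but which pools do is not stated. With the replicate block 18 named-gene results no longer passed and 69 kept their call. In the genotype comparisons this block joined control and labelled transgenic libraries of the same number and cell type, which by label are of different mice. There the lower calls in the erythroid, macrophage, mesothelial and adipocyte lipid lists in APCs numbered 5 in place of 43, and the interferon list in FIPs held 2 lower calls in place of 7. These losses do not bear on shared mice of FIP and APC pools.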

Other observations

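The tests in this part on the genes called in FIPs were chosen after the results were seen, while the random splits were fixed before the data were examined. Bmp6, a growth factor of the BMP family, differed between control FIPs and control APCs. It stood at 7.53 ± 0.03 log2 CPM in FIPs and 5.35 ± 0.20 in APCs (n = 5 each, difference 2.18, limma adjusted p = 5.42e-14), whereas Bmp4 was lower in FIPs (3.57 ± 0.19 against 5.27 ± 0.25, −1.70). Of 29 BMP signaling genes 15 were higher and 5 lower, and 15 and 6 adjusted over the list alone (camera in limma, adjusted p = 0.00244; adjusted p = 0.117 with an estimated correlation). Of 25 TGF-beta response genes 15 were higher and 3 lower, and 16 and 3 adjusted over the list alone (camera adjusted p = 1.79e-05; adjusted p = 0.161 with an estimated correlation). Cell cycle genes were higher for 22 of 32 and lower for 1, and 23 and 1 adjusted over the list alone (camera adjusted p = 0.000185; adjusted p = 0.503 with an estimated correlation).

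Further lists held calls between genotypes in APCs. Of 44 nuclear-encoded oxidative phosphorylation genes 4 fell, and 23 adjusted over the list alone (median −0.17; camera in limma, adjusted p = 1.62e-09; adjusted p = 0.391 with an estimated correlation). Of 20 complement genes 8 fell, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0184; adjusted p = 0.371 with an estimated correlation).

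The genes called in FIPs were scored in APCs, which share no library with them. With the interferon list, other genes named after interferon-induced families and genes with a mean of at most 0.5 log2 CPM in APCs left out, 46 such genes had a mean of 0.06 ± 0.04 in APCs labelled transgenic and −0.06 ± 0.04 in controls (n = 5 each), a difference of 0.13 (exact permutation p = 0.00794, the smallest possible). This could reflect a genotype difference that both populations share, although Zfp423 itself did not follow the label. By the mouse counts FIP and APC pools of a genotype share mice. A difference between the mice other than genotype could therefore appear in both. The genes were also called with a variance estimated from all 20 libraries, APCs included.

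Group labels were split at random 100 times, the real split included. In FIPs 1 split, the real one, reached 65 genes, and the highest other reached 11. With 100 splits, 1 is the smallest number this test can give, so chance is unlikely for that count but not excluded. For FIPs against APCs 1 split of control mice reached 8288 genes, the highest other 1374, and 1 split of mice labelled transgenic reached 7275, the highest other 2150. Every other split mixes the 2 populations, so these counts do not test chance. In APCs 2 splits reached 1396 genes, and the highest other, which exchanged replicate 1 of both groups, reached 2803, so this count follows a structure of the samples and not the genotype labels alone. For the interaction 6 splits reached 2388 genes at an unadjusted p under 0.05, the highest other 3492, and chance cannot be excluded.

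For list counts 54 splits reached the 10 lists of the FIPs (highest other 22) and 13 the 17 lists of the APCs (highest other 21), so chance cannot be excluded for either. Splits of FIPs against APCs keep part of the cell type difference, so their list counts do not test chance: 32 reached the 17 lists of FIPs against APCs in control mice (highest other 23) and 36 the 15 lists in mice labelled transgenic (highest other 21). For the interaction 1 split reached 21 lists, the highest other 20. The correlation of genotype differences across genes, which are not independent replicates, was 0.28, and 2 splits reached it, the highest other being 0.31. The splits for the interaction and for this correlation drew FIP and APC labels independently. Because FIP and APC pools share mice by the mouse counts, these splits do not test chance for either.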
